A study of Mus musculus with 19 samples.

How the data were processed

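RNA from 19 bulk mouse intestinal tumours was measured by sequencing, with libraries made by a TruSeq kit from total RNA extracted with the RNeasy Plus Mini kit. The values are expected counts per Ensembl gene, as deposited by the authors, who per the labels quantified reads with kallisto 0.44.0 on GRCm38.p6. How transcripts were summed to genes and which annotation release was used is not stated. The deposited values are whole numbers with totals that differ between libraries, and no normalization was visible in them. Reads were not processed again. Symbols were found for 28039 identifiers (98.95%) and positions for 28097, in GRCm38 coordinates (GENCODE vM21). Xist has no entry in the table, so sex was checked from Y-linked genes alone.

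Libraries were grouped by genotype and treatment from the sample labels: 6 AP control, 4 AP treated, 6 APP control and 3 APP treated. PBS (4) and IgG (8) controls were pooled. Sex was a covariate. Counts were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests after the default expression filter and TMM normalization. The model held a term for each group and one for sex over the 19 libraries, with 14 residual degrees of freedom, and for PBS against IgG a fit of the 12 controls with sex and genotype, with 8. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are counts per M (mega) of TMM-scaled totals, and log2 CPM used a prior count of 2.

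Library totals were 21.2 M to 35.6 M counts, with the range per group in the report. At a biological coefficient of variation of 0.384, the precision for genes with many counts is set by differences between tumours, whereas counting error limits genes with few counts. Between replicates of a group, chi-square per degree of freedom was 20.5 to 305 over 39 pairs, and 0 pairs of libraries were identical. On simulated counts with 200 changed genes, the tests recovered 38% of 2-fold and 75% of 4-fold changes for genotype in controls, 45% and 76% for treatment in AP, 24% and 64% for treatment in APP, and 20% and 45% for genotype under treatment, with 4.24%, 3.17%, 2.22% and 0% of calls false. The simulation drew each gene independently, without effects of sex or sample prefix. The gene lists of the real data had a median estimated correlation of 0.522, so these shares may not carry over to the tumours.

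Gene lists (33, at least 5 genes each) were fixed before the data were examined, as were the groups, tests, alternatives and rule for naming genes. They were tested with camera in limma 3.58.1 at the preset correlation of 0.01, with camera at an estimated correlation and fry beside it. Lists were adjusted together within each comparison, and members also over the list alone. Named genes were the targets (Prox1, Mmp14, Vegfa, Angpt2, Kdr, Flt1, Tek, Cd40, Cd40lg), the 3 members of smallest p of each called list, and the 5 largest rises and falls among genes with adjusted p under 0.05 and a mean of at least 2 CPM, without predicted, immunoglobulin or T cell receptor genes. The word target covers all genes of that first set, although A2V+CD40 is directed at the products of Vegfa, Angpt2 and Cd40 alone. Genes named outside this rule are marked in the text.

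Alternatives were DESeq2 size factors, DESeq2 1.42.0, limma-voom, no expression filter, a mean of at least 5 CPM, no sex covariate, sex with the sample prefix, the replicate block with sex, IgG controls alone, the groups of the comparison alone, and each library left out in turn. Those written for normalized units (pseudocount, quantile normalization, array weights, TMM on deposited values) did not apply to counts. Robust dispersions, leaving out both libraries of doubtful sex, the endothelial list without Sox17 and contrasts averaged over the other factor were added after the data were seen. Other splits of the libraries were 100 draws for genotype in controls, all 35 for genotype under treatment and 30 for each other comparison, raised from 20 after a first run. The relation between list scores was tested with 100000 permutations and 2000 bootstrap samples.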

Results

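Bulk intestinal tumours of 19 mouse libraries were profiled by RNA sequencing, across 2 genotypes with and without an antibody treatment. AP mice carried floxed Apc and Tp53, a pair of tumour suppressor genes, with a tamoxifen-inducible Cre recombinase under the villin promoter, which is active in intestinal epithelium. APP mice carried a floxed Prox1 gene as well. Prox1 encodes a homeobox transcription factor. Tumours were started with tamoxifen placed in the cecum and grew for 2 weeks, after which the mice were randomized to PBS, a control IgG or A2V+CD40 for 2 weeks. As background, A2V is a bispecific antibody against the vascular growth factors ANGPT2 and VEGFA, and the CD40 part is an antibody that stimulates the CD40 receptor of antigen-presenting cells. The series asks how tumours with and without the floxed Prox1 gene differ and what the treatment does in each.

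There were 6 AP control, 4 AP treated, 6 APP control and 3 APP treated tumours. Each control group pooled 2 PBS and 4 IgG mice. Total counts ran from 21.2 M to 31.7 M in AP control, 22.2 M to 35.6 M in AP treated, 22.9 M to 33.8 M in APP control and 25.5 M to 29.7 M in APP treated libraries. The 17605 genes tested held 99.96% of the counts. The labels give 7 females and 12 males, and all 3 APP treated mice were male. By group, 1 of 6 AP control, 4 of 6 APP control and 2 of 4 AP treated mice were labelled female. AP control 3 and APP control 3, both labelled female, held 107 and 113 CPM over the Y-linked genes, against 104 to 169 CPM in the 12 males and 5.16 to 20.8 CPM in the other 5 females. No AP control tumour thus lay at the level of the other females. The fits used the labelled sex, and none set sex from the Y-linked genes. The second principal component of the 1000 most variable genes, with 14.9% of their variance, parted the genotypes: all 10 AP tumours lay at or below −2.18 and all 9 APP tumours at or above 12.3.

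Prox1 transcripts were present in every tumour. The gene lies on chromosome 1 (190118035 to 190170714, minus strand, GRCm38). AP control tumours 1 to 6 held 285, 262, 249, 231, 211 and 161 CPM of Prox1, and AP treated tumours 1 to 4 held 243, 218, 164 and 206 CPM. APP control tumours 1 to 6 held 221, 188, 158, 203, 177 and 100.4 CPM, and APP treated tumours 2, 3 and 4 held 166, 157 and 205 CPM. The means were 233 ± 43.6 CPM (SD, n = 6) in AP control, 207 ± 33.1 (n = 4) in AP treated, 174 ± 42.2 (n = 6) in APP control and 176 ± 25.3 (n = 3) in APP treated tumours. The log2 fold change of Prox1 in APP against AP control tumours was −0.45 ± 0.19 (SE, adjusted p = 0.604 over all genes tested), which did not pass the test. It was negative in all 17 alternatives, from −0.52 to −0.36. The counts cover the whole gene and the labels do not name the deleted exons, so these values measure transcript from the locus and not the deletion itself.

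**Figure D1:**
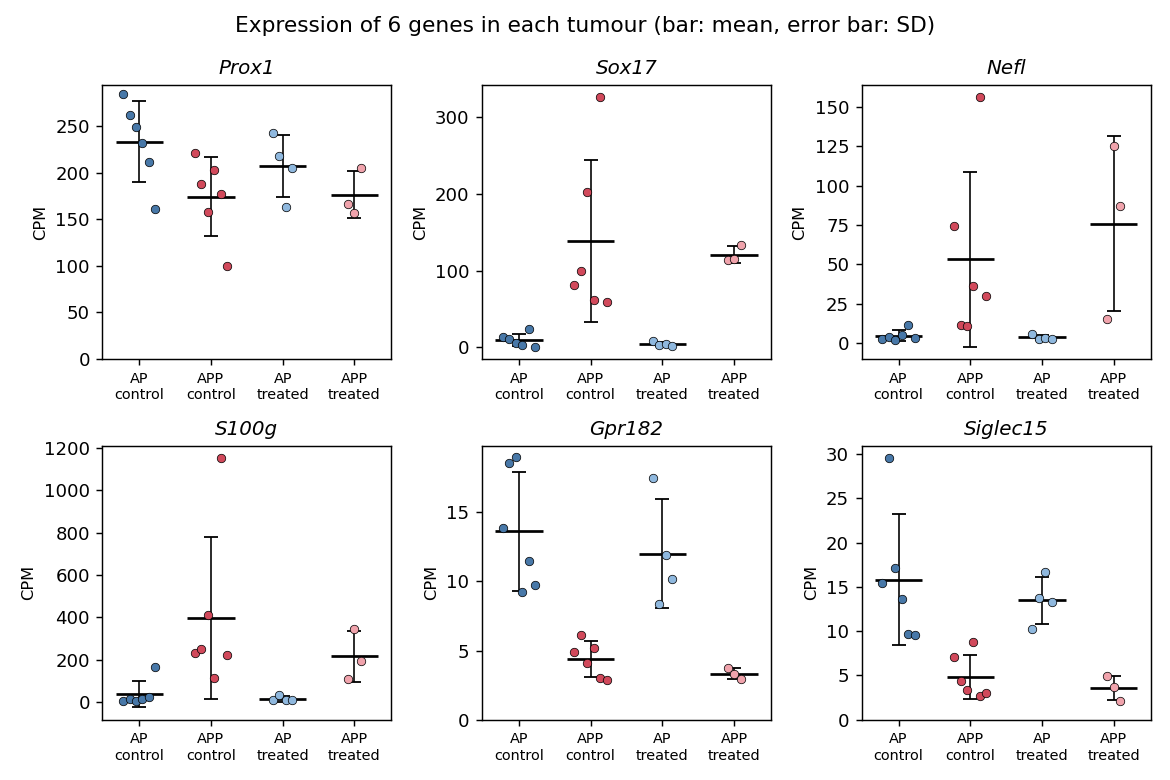
CPM (linear axes) of 6 genes in each of the 19 tumours, by genotype and treatment; points are tumours, thick bars group means and error bars SD. Prox1 means lay between 174 and 233 CPM, whereas the 6 APP control tumours held 138 ± 106 CPM of Sox17 against 9.69 ± 8.26 CPM in the 6 AP control tumours.

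The first comparison asked what the Prox1 genotype changed in control tumours. PROX1 is a transcription factor of lymphatic endothelium and of intestinal secretory and tumour cells. It specifies lymphatic endothelial cells during development. Of the genes tested, 64 were higher and 22 lower in APP than in AP control tumours. Sox17, a transcription factor of endothelium and endoderm on chromosome 1 (4490931 to 4497354), rose from 9.69 ± 8.26 to 138 ± 106 CPM (SD, n = 6 each), a log2 fold change of 4.06 ± 0.66 (SE, adjusted p = 0.00722), with no overlap between the groups. S100g, which encodes the calcium-binding protein calbindin-D9k, rose from 37.3 ± 63.0 to 396 ± 383 CPM (4.39 ± 0.88, adjusted p = 0.0341). Khdc1a rose from 0.833 to 9.37 CPM (4.33 ± 0.65, adjusted p = 0.00361). Gabrp, a GABA receptor subunit, rose from 0.552 to 6.83 CPM (3.88 ± 0.69, adjusted p = 0.0148). Ifi202b, an interferon-inducible gene, was also called (adjusted p = 0.0161), with 3110 counts over the 6 APP control libraries and 4 over the 6 AP control libraries. Its ratio per total count was 810 (95% exact interval 316 to 2973, counting error alone), and APP control 5 held 1 count, as did APP treated 4, against 124 to 1390 in the other 7 APP tumours.

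Among the falls, Hist1h2bc, a histone H2B gene, went from 99.0 ± 12.3 to 31.0 ± 5.36 CPM (−1.75 ± 0.17, adjusted p = 0.000242, the smallest of this comparison). Gpr182, a G protein-coupled receptor gene, fell from 13.6 ± 4.30 to 4.37 ± 1.28 CPM (−1.75 ± 0.26, adjusted p = 0.00309). The others with the largest falls were Siglec15, a sialic acid-binding lectin (−1.81 ± 0.39, adjusted p = 0.0494), Sgip1 (−1.65 ± 0.35, adjusted p = 0.0443) and Ptprz1, a receptor tyrosine phosphatase (−1.61 ± 0.29, adjusted p = 0.0177). The other histone calls went both ways: Hist1h2br and Hist1h2bq rose by 3.43 and 3.17 on the log2 scale and Hist1h2bj fell by 3.52. These H2B paralogs are alike in sequence, so the member that changed is uncertain. The H4 gene Hist1h4m was called lower as well (adjusted p = 0.0494), with a mean of 0.685 CPM in AP and listed at 0 in APP control tumours. Chosen after their values were seen, the neurofilament genes Nefl and Nefm rose by 3.74 ± 0.71 and 3.78 ± 0.54 (adjusted p = 0.0223 and 0.00248). Nefl lies within the span of Nefm on the opposite strand, so reads shared between them cannot be excluded.

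The treatment targets did not pass in this comparison: Mmp14 had a log2 fold change of −0.21, Vegfa 0.0043, Angpt2 0.24, Kdr 0.11, Flt1 0.25, Tek 0.20, Cd40 0.12 and Cd40lg −0.85, with adjusted p = 0.9996 for each. Single left-out libraries moved these by over 1.5 times: Mmp14 −0.31 to −0.0753, Vegfa −0.11 to 0.0825, Angpt2 0.045 to 0.34, Kdr −0.0871 to 0.36, Flt1 0.11 to 0.34, Tek 0.12 to 0.36, Cd40 −0.57 to 0.36 and Cd40lg −1.68 to −0.25. Blood endothelial genes ranked higher in APP control tumours, with 17 of 19 members positive and a median of 0.28. This call, like the 3 other list calls of this paragraph, was lost at adjusted p = 0.904 with an estimated correlation. Of these, Sox17 alone passed over all genes and also adjusted over the list alone, and the other 18 members had a median of 0.26. Cdh5, the endothelial cadherin, had 1.17 ± 0.38 (adjusted p = 0.278) and Esam 0.76 ± 0.26 (adjusted p = 0.336). Fibroblast and matrix genes were positive in 22 of 25 (median 0.35, Lum 1.04, Dcn 0.38, Col6a3 0.55) and tip cell genes in 10 of 13 (median 0.36, Esm1 1.49, Aplnr 1.36, Apln 1.27), with 0 members passing in either, over all genes or adjusted over the list alone. Interferon-gamma response genes were negative in 25 of 26 (median −0.35, Gbp6 −1.21, Irf8 −0.37, Irf1 −0.35), again with 0 members passing. Single libraries moved several of these members: without APP control 2, Irf8 was −0.0145, Irf1 −0.0240, Lum 0.64, Esm1 0.89 and Apln 0.61, without AP control 5, Gbp6 was −0.59 and Col6a3 0.88, without APP control 5, Gbp6 was −2.92 and Irf1 −0.72, without AP control 3, Irf8 was −0.68 and Col6a3 0.33, and without AP control 6, Dcn was 0.24. Over all alternatives, Apln fell as low as 0.20, Col6a3 0.081, Esm1 0.66 and Dcn 0.17.

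These 4 lists had adjusted p of 2.83e-05, 0.000128, 0.0155 and 0.00565 by camera with its preset correlation. None held with an estimated one: adjusted p = 0.904 with an estimated correlation for each, and 0.926 by fry. The other 29 lists had adjusted p between 0.0821 and 0.980. With IgG controls alone, the interferon-gamma list turned higher in APP (adjusted p = 0.00642), the tip cell and endothelial lists lost their calls (0.838 and 0.0532), and the fibroblast call stayed. The number of lists called was 10 in that fit, 9 and 8 without AP control 1 and 6, and 2 and 12 without APP control 3 and 5. The interferon-gamma call also ended without AP control 4 (0.0811), APP control 2 (0.929) or APP control 3 (0.189), or without the sex covariate (0.145). The tip cell call ended without the 2 libraries of doubtful sex (0.0661), and without AP control 6 (0.121), APP control 1 (0.0540), APP control 2 (0.320) or APP control 3 (0.0638). Over the list alone, 6 genes passed in any list: Sox17, Kit (1.09 ± 0.17, 4.23e-05), Adam12 (−1.18, 0.00535), Lcn2 (−1.71, 0.00857), Ctla4 (−5.24, 0.0115, from a mean of 2.75 to 0.117 CPM) and Tgfb2 (1.25, 0.0123).

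The 86 calls became 270 with DESeq2, which held all of them, 53 with limma-voom and 137 without the sex covariate. They became 32 from these groups alone with the expression filter set anew (16428 genes; 40 over the 17605 genes, which hold all 32), 26 without the 2 libraries of doubtful sex, 25 for genes of at least 5 CPM, and 13 with IgG controls alone, 10 of them shared. Of the 10 named genes, Hist1h2bc alone kept its call with IgG controls alone (Sox17 4.13, adjusted p = 0.161; Ifi202b 3.69, adjusted p = 0.914), and Sox17, Khdc1a and Hist1h2bc kept theirs without the 2 libraries of doubtful sex. Left-out libraries moved the count to 20 without APP control 5, 42 and 44 without AP control 3 and 4, and 57 without APP control 3. In those fits Hist1h2bc and Gpr182 kept their calls without any single library. Sox17 (log2 fold change 3.41, adjusted p = 0.0870), Khdc1a (3.57) and Gabrp (3.80) lost theirs without APP control 5, and Ptprz1 without AP control 3 (0.115) or APP control 5 (0.103). Ifi202b lost its call without AP control 3 (0.0799), AP control 4 (0.0508) or APP control 2 (0.554). S100g lost it without AP control 2, 3, 4 or 5 or APP control 1, 3 or 5 (0.0509 to 0.254), Siglec15 without AP control 1 to 4 or APP control 1, 2, 3, 5 or 6 (0.0521 to 0.240), and Sgip1 without any single library other than AP control 5 and APP control 6 (0.0571 to 0.252).

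The second comparison asked what A2V+CD40 changed in AP tumours. VEGFA and ANGPT2 act on the endothelial receptors KDR and TEK, and stimulation of CD40 on antigen-presenting cells primes T cells. Type I interferon genes respond to antiviral and immune signals, and hypoxia genes to a shortage of oxygen. Type I interferon response genes ranked higher in the 4 treated than in the 6 control tumours, with all 19 members positive and a median log2 fold change of 0.66 (Ifit3 1.03 ± 0.55, Oas2 0.89 ± 0.50, Oasl1 0.74 ± 0.40). This call was lost at adjusted p = 0.769 with an estimated correlation, and the other 4 of this paragraph at 0.319 to 0.918. Ifit3 averaged 150 ± 96.9 CPM in treated and 78.3 ± 36.4 CPM in control tumours. Red blood cell genes ranked lower in all 7 members (median −1.91, Hbb-bt −2.44, Hbb-bs −2.11, Gypa −1.86), and blood endothelial genes in 18 of 19 (median −0.36, Kdr −0.58 ± 0.39, Tie1 −0.45, Tek −0.38 ± 0.25). Over all alternatives the smallest falls were −1.37 for Hbb-bt, −0.98 for Hbb-bs and −0.998 for Gypa, in settings other than leaving out 1 library. Treatment was partly confounded with control kind, prefix and age in both genotypes. No treated mouse carried the sample prefix of the PBS controls. Treated mice were 8 to 10 weeks old, and PBS controls 12. Red blood cell genes also ranked higher, and type I interferon genes lower, in PBS than in IgG tumours. The AP calls of both lists stayed with IgG controls alone at the preset correlation. Hypoxia and glycolysis genes were positive in 16 of 21 (median 0.26, Pdk1 0.47, Ldha 0.43, Pgk1 0.43). B cell and plasma cell genes were positive in 14 of 17 (median 0.85, Ms4a1 1.77, Ighm 1.59, Bank1 1.48). Without AP treated 3, Ifit3 was 0.50, Oasl1 0.49 and Pgk1 0.24, without AP treated 4, Oas2 was 0.53, without AP treated 2, Ighm was 0.57, Ms4a1 −0.0318 and Bank1 −0.29, and without AP control 5, Kdr was −0.34, Tie1 −0.26 and Tek −0.23.

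Epithelial genes were positive in 15 of 16 (median 0.23, Krt19 0.30, Elf3 0.25, Cdh1 0.22), smooth muscle genes in 13 of 13 (median 0.61), proliferation genes in 19 of 20 (median 0.11) and goblet cell genes in 12 of 15 (median 0.32). The epithelial call was lost at adjusted p = 0.769 with an estimated correlation and the other 3 at 0.957. Differentiated absorptive cell genes tested as higher although their median was −0.02 and their mean −0.15: Ms4a12 had 1.01, Ceacam20 0.74 and Clca4a 0.66, while 11 of 19 members were negative. That call was lost at adjusted p = 0.769 with an estimated correlation. Without AP control 3, Ceacam20 was 0.40 and Cdh1 0.15, without AP treated 1, Krt19 was 0.17, without AP treated 2, Clca4a was 0.39, without AP treated 3, Elf3 was 0.16, and without AP treated 4, Elf3 was 0.38 and Krt19 0.45. Over all alternatives Ceacam20 and Cdh1 each fell as low as 0.0855. In AP control 6 the absorptive score was 7.97, against 4.97 in the next AP control tumour. In none of the 10 lists did a member pass, over all genes or adjusted over the list alone. Of the treatment targets, Prox1 had −0.19, Mmp14 −0.0676, Vegfa 0.0118, Angpt2 −0.0891, Flt1 −0.34, Cd40 −0.31 and Cd40lg −0.0124. Over the fits without 1 library each moved by over 1.5 times: Prox1 −0.27 to −0.0692, Mmp14 −0.29 to 0.037, Vegfa −0.10 to 0.12, Angpt2 −0.36 to 0.0636, Flt1 −0.50 to −0.16, Cd40 −0.54 to −0.16 and Cd40lg −0.61 to 0.48.

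By edgeR 0 genes passed, with 340 at an unadjusted p under 0.05 and 880 due by chance. DESeq2 called 4, named because they fall outside the naming rule and seen first (H2-Ea-ps, Ptges3-ps, Rpl14-ps1 and Tmem92), and limma-voom 0. Their log2 fold changes by DESeq2 were 8.96, 21.8, −3.21 and 1.20, and a value as large as 21.8 cannot be read as an effect size. From these groups alone edgeR called 1, Rpl14-ps1. Without AP control 6 the count under 0.05 was 874. The 10 lists had camera adjusted p of 5.66e-07 (type I interferon), 7.03e-06 (red blood cell), 1.59e-05 (hypoxia), 2.00e-05 (absorptive), 6.18e-05 (epithelial), 7.79e-05 (B cell), 0.00143 (endothelial), 0.00759 (smooth muscle), 0.0184 (proliferation) and 0.0361 (goblet). None held: adjusted p = 0.319 with an estimated correlation for hypoxia, 0.767 to 0.957 for the other 9, and fry 0.848 to 0.970. The other 23 lists had adjusted p between 0.0920 and 0.994.

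The type I interferon, red blood cell and hypoxia calls stayed in all 10 fits that left out 1 library. The B cell call ended without AP treated 2 (0.157), and the endothelial call without AP control 5 (0.170) or AP treated 2 (0.286). The absorptive and epithelial calls ended without AP control 3 (0.240 and 0.0959) with IgG controls alone (0.601 and 0.530) and without the 2 libraries of doubtful sex (0.358 and 0.146), and the absorptive call also with the sample prefix added (0.116). The smooth muscle call ended without AP control 3 or 4 or AP treated 1 or 3 (0.447, 0.0593, 0.0757 and 0.924), with the sample prefix added (0.188), with IgG controls alone (0.494) and without the 2 libraries of doubtful sex (0.709). The proliferation call ended without AP control 1, 5 or 6 or AP treated 3 or 4 (0.171, 0.0788, 0.261, 0.826 and 0.566) and without the sex covariate (0.0784), and the goblet call with IgG controls alone (0.420) and without AP control 4, 5 or 6 or AP treated 1, 2 or 3 (0.151, 0.0676, 0.213, 0.478, 0.156 and 0.240).

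**Figure D2:**
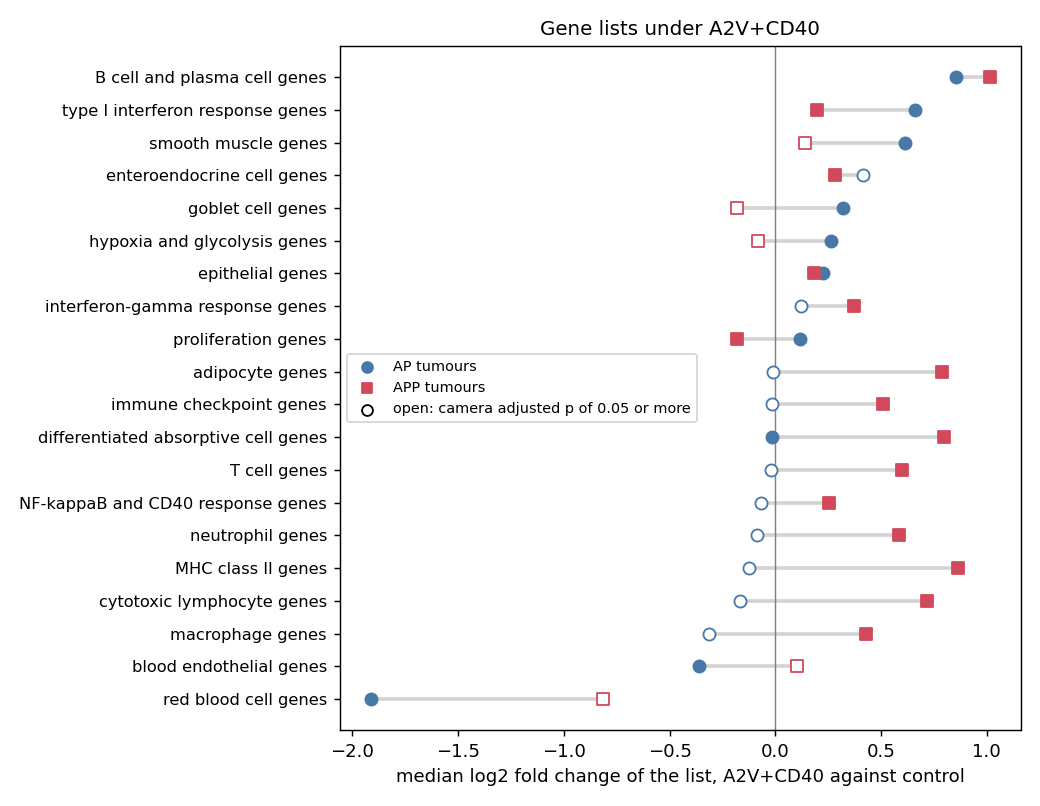
Median log2 fold change under A2V+CD40 of each gene list called in either genotype (horizontal axis), for AP (circles) and APP tumours (squares); filled symbols have a camera adjusted p under 0.05 at the preset correlation, and none was called with an estimated correlation. Red blood cell genes had a median of −1.91 in AP tumours and T cell genes 0.60 in APP tumours.

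The third comparison asked the same of APP tumours. T cells and cytotoxic lymphocytes kill tumour cells through perforin and granzymes, and B cells present antigen and make antibodies. Neutrophils follow the chemokine receptor CXCR2 into tissue. T cell genes ranked higher in the 3 treated than in the 6 control tumours, with all 20 members positive and a median log2 fold change of 0.60. This call, like the other 5 of this paragraph, was lost at adjusted p = 0.844 with an estimated correlation. Cd3d, a subunit of the T cell receptor complex, averaged 11.2 ± 0.882 CPM in treated and 6.58 ± 2.53 CPM in control tumours (1.16 ± 0.44), and Cd8b1 had 2.26 ± 0.93. Cytotoxic lymphocyte genes were positive in 14 of 14 (median 0.72, Prf1, the perforin gene, 1.83 ± 0.86, Gzmk 1.78), and B cell and plasma cell genes in 17 of 17 (median 1.01, Cd79a 2.11, Cd79b 1.77, Cd22 1.28). Neutrophil genes were positive in 16 of 16 (median 0.59, Cxcr2 0.86 ± 0.35, Lcn2 0.72, Cxcl1 0.65) and differentiated absorptive cell genes in 18 of 19 (median 0.80, Aqp8 3.30, Apoa1 2.15, Ceacam20 1.02). Proliferation genes were negative in 20 of 20 (median −0.18, Pcna −0.35, Bub1 −0.34, Cenpa −0.30). Single treated tumours carried several of these values: without APP treated 3, Gzmk was 0.32, Prf1 1.10, Cd8b1 1.20, Cxcr2 0.52 and Cenpa −0.15, without APP treated 4, Cd79b was 0.10, Cd79a 0.63, Cd22 −0.20, Cxcl1 0.17 and Cenpa −0.48, and without APP treated 2, Aqp8 was 2.16. Without the control tumour APP control 5, Ceacam20 was 0.58, Pcna −0.0850, Gzmk 3.05 and Prf1 2.75.

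Interferon-gamma response genes were positive in 19 of 26 (median 0.37, Cxcl11 1.06, Irgm1 0.60, Stat1 0.47), type I interferon genes in 17 of 19 (median 0.20), immune checkpoint genes in 10 of 11 (0.51), MHC class II genes in 9 of 9 (0.86), macrophage genes in 18 of 20 (0.43), NF-kappaB and CD40 response genes in 13 of 15 (0.25), adipocyte genes in 9 of 9 (0.79), enteroendocrine genes in 8 of 15 (0.28) and epithelial genes in 13 of 16 (0.18). Both interferon calls were lost at adjusted p = 0.875 with an estimated correlation and the other 7 at 0.844. Without APP treated 3, Cxcl11 was −0.69, Irgm1 −0.32 and Stat1 −0.26, and without APP control 5, Irgm1 was 1.43 and Stat1 0.95. In the 15 lists 0 members passed over all genes, and adjusted over the list alone only Apoa1, an apolipoprotein gene, passed (0.0187), at 18.4 ± 22.9 CPM in treated and 4.32 ± 0.354 CPM in control tumours. Its log2 fold change of 2.15 was 0.34 without APP treated 2, so it rests on that library. The treatment targets had log2 fold changes of 0.21 for Mmp14, −0.33 for Vegfa, −0.31 for Angpt2, 0.19 for Kdr, −0.0094 for Flt1, −0.13 for Tek, 0.37 for Cd40, 0.80 for Cd40lg and 0.0531 for Prox1. Each moved by over 1.5 times when 1 library was left out: Prox1 −0.0703 to 0.14, Mmp14 0.14 to 0.28, Vegfa −0.63 to 0.0938, Angpt2 −0.45 to −0.0946, Kdr −0.0016 to 0.29, Flt1 −0.21 to 0.13, Tek −0.28 to 0.00773, Cd40 −0.00725 to 1.16 and Cd40lg 0.16 to 1.26.

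By edgeR 0 genes passed, with 291 at an unadjusted p under 0.05. DESeq2 called 5, named after they were seen (Pla2g2d, Igkv8-18, Gm10241, Gm13835 and Gm21983), and limma-voom 0. The 15 lists had camera adjusted p of 2.51e-06 (T cell), 6.31e-05 (neutrophil), 0.000119 (absorptive), 0.000228 (B cell and cytotoxic), 0.00269 (proliferation), 0.00318 (interferon-gamma), 0.00742 (checkpoint), 0.0110 (type I interferon), 0.0120 (enteroendocrine, MHC class II and NF-kappaB), 0.0142 (adipocyte), 0.0150 (macrophage) and 0.0182 (epithelial). None held: adjusted p = 0.875 with an estimated correlation for both interferon lists, 0.844 for the other 13, and fry 0.988. The other 18 lists had adjusted p between 0.0860 and 0.992.

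With IgG controls alone both interferon lists turned lower in treated APP tumours (interferon-gamma adjusted p = 0.00449, type I 0.0252), and the T cell, neutrophil, B cell and cytotoxic calls ended (0.0880, 0.516, 0.284 and 0.885), as did the macrophage, checkpoint and NF-kappaB calls (0.253, 0.301 and 0.525), while the MHC class II list turned (0.824). With the sample prefix added, the absorptive (0.160), proliferation, enteroendocrine and adipocyte (each 0.341) and epithelial calls (0.394) ended. Without the sex covariate, the interferon-gamma and macrophage (both 0.242), checkpoint (0.0551), enteroendocrine (0.498), MHC class II (0.331), adipocyte (0.358) and epithelial calls (0.171) ended. The macrophage call also ended without the expression filter (0.0723), and the NF-kappaB call without the 2 libraries of doubtful sex (0.0518). Single libraries also mattered. Without APP treated 3 the list count was 8: the interferon-gamma and macrophage lists turned (both 0.961), and the cytotoxic, checkpoint, type I interferon, MHC class II, enteroendocrine and epithelial calls ended (0.469, 0.453, 0.883, 0.903, 0.306 and 0.453). Without APP treated 4 it was 7: the neutrophil, B cell, proliferation, interferon-gamma, checkpoint, type I interferon, MHC class II, NF-kappaB and macrophage calls ended (0.128, 0.685, 0.140, 0.135, 0.160, 0.160, 0.200, 0.488 and 0.163). Without APP treated 2 the adipocyte and enteroendocrine calls ended (0.662 and 0.145). Without APP control 2 both interferon lists turned (0.702 and 0.547) and the cytotoxic, checkpoint, MHC class II, NF-kappaB, adipocyte and macrophage calls ended (0.125, 0.120, 0.530, 0.125, 0.137 and 0.0878). Without APP control 5 the proliferation, enteroendocrine and epithelial calls ended (0.238, 0.778 and 0.938), without APP control 3 the type I interferon call (0.0603) and without APP control 6 the macrophage call (0.0562). The T cell and absorptive calls stayed in all 9 fits that left out 1 library, though the T cell call ended with IgG controls alone and the absorptive call with the sample prefix added.

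The fourth comparison tested whether the treatment effect differed between genotypes. Proliferation genes mark dividing cells, and T cell and cytotoxic genes mark lymphocytes in the tumour. Endothelial genes mark blood vessels and the red blood cell genes the blood within them. At the preset correlation of camera, the effect in APP tumours ranked lower than in AP for proliferation genes (20 of 20 members negative, median −0.27, Bub1 −0.63, Pcna −0.56, Mki67 −0.40) and for hypoxia and glycolysis genes (15 of 21 negative, median −0.22, Bnip3 −0.95, Pdk1 −0.79, Pgk1 −0.40). It ranked higher for T cell genes (19 of 20 positive, median 0.66, Cd3d 0.89), cytotoxic lymphocyte genes (13 of 14, 0.90, Prf1 1.81), neutrophil genes (15 of 16, 0.69, Cxcr2 1.06), blood endothelial genes (18 of 19, 0.33, Eng 1.07, Kdr 0.77) and red blood cell genes (7 of 7, 1.27, Hbb-bt 1.56). All 7 differences were lost at adjusted p = 0.960 with an estimated correlation and 0.984 by fry. Without APP control 5, Pcna was −0.24 and Prf1 3.08, without AP control 3, Mki67 was −0.23 and Pcna −0.87, without APP treated 3, Prf1 was 1.07 and Eng 0.65, without AP treated 3, Pgk1 was −0.14, and without APP control 2, Hbb-bt was 3.58. Members passing in these lists numbered 0, over all genes or adjusted over the list alone. Mmp14 had 0.28, Vegfa −0.35, Angpt2 −0.22, Flt1 0.33, Tek 0.25, Cd40 0.68, Cd40lg 0.81 and Prox1 0.24. These too moved by over 1.5 times without 1 library: Prox1 0.0807 to 0.32, Mmp14 0.10 to 0.57, Vegfa −0.64 to 0.0735, Angpt2 −0.43 to 0.0586, Flt1 0.0885 to 0.51, Tek 0.10 to 0.39, Cd40 0.29 to 1.67 and Cd40lg −0.0457 to 2.01.

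By edgeR 0 genes differed in their treatment effect, with 256 at an unadjusted p under 0.05. DESeq2 called 1, Gm13835, named after it was seen, and limma-voom 0. Its log2 fold change by DESeq2, −27.6, cannot be read as an effect size. The 7 lists had camera adjusted p of 0.000263 (proliferation), 0.00577 (T cell), 0.00654 (red blood cell), 0.0109 (hypoxia and endothelial), 0.0170 (neutrophil) and 0.0172 (cytotoxic). None held, at adjusted p = 0.960 with an estimated correlation and 0.984 by fry, and the other 26 lists lay between 0.0541 and 0.936. With IgG controls alone the neutrophil and cytotoxic lists turned (0.174 and 0.672) and the T cell and hypoxia calls ended (0.842 and 0.619). Without the sex covariate, the T cell (0.588), red blood cell (0.486), cytotoxic (0.435) and hypoxia calls (0.0777) ended, and without the 2 libraries of doubtful sex, the neutrophil (0.8293), red blood cell (0.149) and endothelial calls (0.0713). The T cell call ended without APP control 2, APP treated 3 or APP treated 4 (0.259, 0.355 and 0.0572), the red blood cell call also without AP control 3 or APP control 5 (0.174 and 0.192), the hypoxia call without APP control 2 (0.149) and the proliferation call without AP treated 3 (0.0852). The endothelial call ended without AP control 3, AP control 5, AP treated 2 or APP treated 3 (0.0602, 0.0670, 0.328 and 0.248). The neutrophil call ended without AP control 3, 4 or 5, APP control 2 or APP treated 4 (0.776, 0.0555, 0.0588, 0.259 and 0.402), and the cytotoxic call without AP control 4 or 5, AP treated 2, APP control 2 or APP treated 3 (0.0674, 0.0588, 0.0865, 0.695 and 0.510). The number of lists was 13 and 14 without AP control 1 and 6, 15 and 16 without APP control 5 and APP treated 2, and 4 without AP control 5.

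The fifth comparison asked what the Prox1 genotype changed under A2V+CD40. Neurofilaments are structural proteins of neurons, matrilins are proteins of the extracellular matrix, and CDH5 holds endothelial cells together. Dendritic cells take up antigen and present it to T cells. All 11 genes called were higher in the 3 APP than in the 4 AP treated tumours, without overlap in the 5 named by rule, and 847 genes had an unadjusted p under 0.05, where 880 are due by chance. Nefm, a neurofilament gene, rose from 0.779 ± 0.269 to 16.9 ± 9.93 CPM (4.05 ± 0.71, adjusted p = 0.0497). Duox1, which encodes an oxidase that makes hydrogen peroxide, rose from 0.442 to 4.47 CPM (3.49 ± 0.58, adjusted p = 0.0436), Cpxm2 from 2.21 to 18.8 CPM (2.82 ± 0.50, adjusted p = 0.0497), Matn4, a matrix protein gene, from 0.861 to 5.46 CPM (2.56 ± 0.42, adjusted p = 0.0436) and Ap3b2 from 1.28 to 7.01 CPM (2.46 ± 0.39, adjusted p = 0.0436). Of the 11 genes, 9 were also among the 86 of the control tumours, and 84 of those 86 had the same sign in treated tumours. With each treatment arm fitted on its own over the same 17605 genes, all 40 genes called in control tumours had the same sign in treated tumours and 36 had p under 0.05 there. Of all genes in those fits, 56.9% had the same sign. Sox17 held 4.60 ± 2.78 CPM in AP and 121 ± 11.1 CPM in APP treated tumours, but did not pass over all genes (4.39 ± 0.88, adjusted p = 0.0954).

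**Figure D3:**
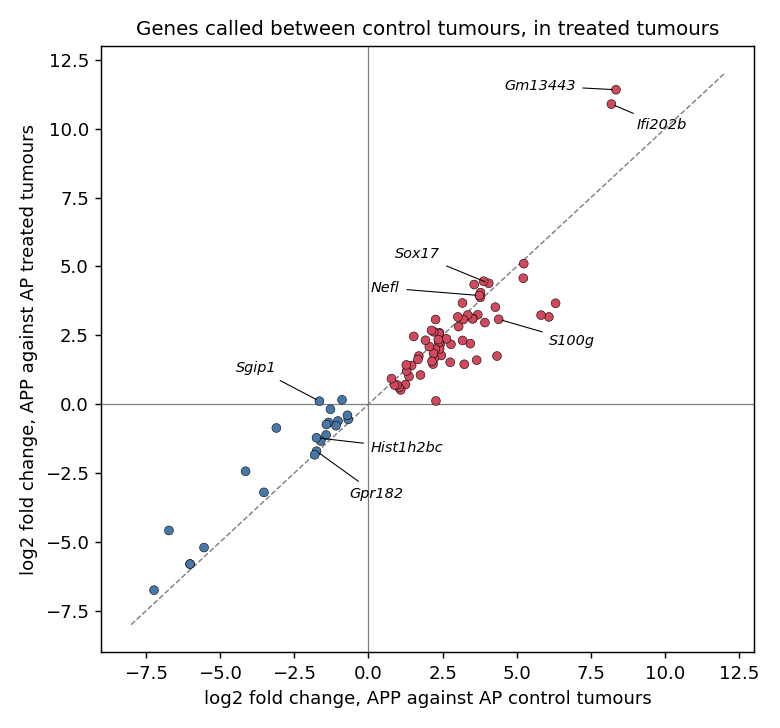
Log2 fold change of each of the 86 genes called between APP and AP control tumours (horizontal axis) against its log2 fold change between APP and AP treated tumours (vertical axis); red points rose and blue points fell in control tumours, and the dashed line marks equal values. In treated tumours 84 of the 86 genes had the same sign.

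Blood endothelial genes were positive in 18 of 19 (median 0.68), and adjusted over the list alone 2 passed: Sox17 (0.00216) and Cdh5 (1.83 ± 0.51, 0.0200, over all genes 0.328). This list call, like the 8 others of this paragraph, was lost at adjusted p = 0.806 with an estimated correlation. Tip cell genes were positive in 10 of 13 (median 0.70), fibroblast and matrix genes in 24 of 25 (0.58, Bgn 1.03, Thy1 0.78, Pdgfrb 0.73), dendritic cell genes in 14 of 14 (0.70, Clec9a 1.80, Fscn1 1.10, Ccl22 0.99), TGF-beta response genes in 11 of 14 (0.43) and red blood cell genes in 7 of 7 (0.92). Proliferation genes were negative in 20 of 20 (median −0.26, Pcna −0.74, Foxm1 −0.42, Mki67 −0.30), hypoxia and glycolysis genes in 19 of 21 (−0.23, Pdk1 −0.75, Bnip3 −0.73, Ero1l −0.45) and type I interferon genes in 19 of 19 (−0.50). In these other 8 lists 0 members passed by either adjustment. Without APP treated 3, Bgn was 0.51, without APP treated 4, Ccl22 was 0.55, and without AP treated 4, Foxm1 was −0.26 and Mki67 −0.17. The treatment targets did not pass either: Mmp14 0.0719, Vegfa −0.34, Angpt2 0.0146, Kdr 0.88, Flt1 0.58, Tek 0.45, Cd40 0.80, Cd40lg −0.0407 and Prox1 −0.20. With 1 library left out, Prox1 −0.34 to −0.13, Mmp14 −0.00514 to 0.31, Vegfa −0.64 to 0.0776, Angpt2 −0.15 to 0.27, Flt1 0.37 to 0.72, Tek 0.29 to 0.59, Cd40 0.41 to 1.18 and Cd40lg −0.27 to 0.20 were the ranges of those moved by over 1.5 times.

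The 9 lists had camera adjusted p of 2.73e-12 (endothelial), 0.000458 (proliferation), 0.000845 (fibroblast), 0.00145 (dendritic), 0.0140 (hypoxia), 0.0250 (TGF-beta and tip cell), 0.0308 (type I interferon) and 0.0335 (red blood cell). None held, at adjusted p = 0.806 with an estimated correlation and fry 0.807 to 0.853, and the other 24 lists lay between 0.0503 and 0.722. The endothelial list stayed called without each library in turn. The proliferation, fibroblast, dendritic and hypoxia calls each ended without 1 library (AP treated 3, 0.0794; APP treated 3, 0.0740; APP treated 4, 0.0823; AP treated 1, 0.0943). The TGF-beta call ended without AP treated 1 or APP treated 3 (0.0613 and 0.162) and the tip cell call without AP treated 1, AP treated 3 or APP treated 4 (0.0613, 0.0549 and 0.0955). The type I interferon call ended without AP treated 3, AP treated 4 or APP treated 2 (0.547, 0.102 and 0.818), and the red blood cell call without AP treated 3, AP treated 4, APP treated 2 or APP treated 3 (0.0794, 0.0940, 0.111 and 0.152). Without the 2 libraries of doubtful sex, the TGF-beta (0.0758), tip cell (0.0536), type I interferon (0.132) and red blood cell calls (0.188) ended, as did the type I interferon call with the sample prefix added (0.335) and the red blood cell call without the sex covariate (0.325). The number of lists was 5 without AP treated 3 and 17 without APP treated 2.

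The 11 calls became 116 with DESeq2, which held all of them, and 36 without the sex covariate. They became 0 for genes of at least 5 CPM, with the sample prefix added, without the 2 libraries of doubtful sex, and from these groups alone; 2 with IgG controls alone (Duox1 and Pcna-ps2), and 7 with robust dispersions. Leaving out APP treated 2 gave 5 (Nefm, Matn4, Ap3b2, Dnah6 and Tal2), AP treated 2 gave 3 (Hist1h2bc, Hist1h2br and Hist1h2bq), and AP treated 1, 3 or 4 or APP treated 3 or 4 gave 0. In those fits Duox1 and Cpxm2 lost their calls without any 1 of the 7 libraries, and Nefm, Matn4 and Ap3b2 without any but APP treated 2. The other calls were Dnah6, Gm13443, Gm14226, Kcna6, Tal2 and Rbpjl, and these gene names were taken after the values were seen.

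The last comparison asked whether the PBS and IgG controls differed. Paneth cells of the intestinal crypt secrete lysozyme, angiogenin 4 and other antimicrobial proteins. Red blood cell genes reflect blood in the sample, and adipocyte genes fat attached to it. Red blood cell genes ranked higher in the 4 PBS than in the 8 IgG tumours, with all 7 members positive (median 2.01) and all 7 passing adjusted over the list alone: Slc4a1 averaged 2.78 and 0.365 CPM and Hba-a2 182 and 40.2 CPM. This call was lost at adjusted p = 0.216 with an estimated correlation, and the other 4 of this paragraph at 0.216 to 0.570. Paneth cell and antimicrobial genes ranked higher as well (8 of 10 positive, median 1.33, 6 passing adjusted over the list alone). Itln1, an intestinal lectin, averaged 1787 ± 1192 CPM (n = 4) and 237 ± 78.5 CPM (n = 8) (2.80 ± 0.42, adjusted p = 0.147), Lyz1, a Paneth cell lysozyme, 6315 and 841 CPM, and Ang4 1626 and 224 CPM. Interferon-gamma response genes ranked lower in 26 of 26 members (median −1.08, Nlrc5 −1.70, Gbp7 −1.45, Irf1 −0.84), as did type I interferon genes (19 of 19, −0.92, Ifit1 −1.25, Oas3 −1.14) and adipocyte genes (9 of 9, −1.42, Retn −2.65, Adrb3 −1.42, Fabp4 −1.12), of which 7 passed adjusted over the list alone. Without APP control 2, Nlrc5 was −0.98, Gbp7 −0.78, Irf1 −0.47 and Ang4 1.81, and without AP control 2, Gbp7 was −2.22 and Irf1 −1.34.

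B cell and plasma cell genes were negative in 16 of 17 (median −1.74, Cd79a −2.36), differentiated absorptive cell genes in 17 of 19 (−1.61, Ms4a12 −1.15, adjusted over the list alone 0.0228), dendritic cell genes in 13 of 14 (−0.77, Siglech −2.01, adjusted over the list alone 0.00285), cytotoxic lymphocyte genes in 14 of 15, MHC class II genes in 9 of 9 (−0.99), T cell genes in 17 of 20 (−0.59) and smooth muscle genes in 12 of 13 (−0.28). Goblet cell genes were positive in 13 of 15 (0.52), WNT target and stem cell genes in 21 of 22 (0.19), mast cell genes in 9 of 9 (0.70), TGF-beta response genes in 10 of 14 (0.27) and matrix metalloproteinases and inhibitors in 10 of 16 (0.11, Mmp7 0.86, adjusted over the list alone 0.0486). All 12 calls of this paragraph were lost, at adjusted p = 0.570 to 0.757 with an estimated correlation. The treatment targets had log2 fold changes of 0.16 (Mmp14), 0.13 (Vegfa), 0.20 (Angpt2), −0.45 (Kdr), 0.22 (Flt1), −0.21 (Tek), −0.50 (Cd40), −1.69 (Cd40lg) and 0.0901 (Prox1). All moved by over 1.5 times in a fit without 1 library: Prox1 −0.00945 to 0.18, Mmp14 0.0543 to 0.29, Vegfa −0.12 to 0.37, Angpt2 0.0513 to 0.31, Kdr −0.64 to −0.16, Flt1 0.12 to 0.43, Tek −0.26 to −0.10, Cd40 −0.75 to −0.0312 and Cd40lg −4.90 to −1.18.

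By edgeR 0 of 17761 genes passed, with 1832 at an unadjusted p under 0.05 against 888 due by chance. DESeq2 called 180 (90 higher, 90 lower) and limma-voom 1, Gm15293; without AP control 1 edgeR called 1, Clca4b, and both were named after they were seen. The 17 lists had camera adjusted p of 1.64e-08 (red blood cell), 9.18e-08 (interferon-gamma), 1.13e-06 (type I interferon), 2.58e-06 (adipocyte), 4.00e-06 (Paneth), 7.45e-05 (B cell), 9.52e-05 (absorptive), 9.64e-05 (goblet), 0.000163 (dendritic), 0.000262 (WNT), 0.000753 (cytotoxic), 0.00103 (MHC class II), 0.00414 (mast cell), 0.0303 (TGF-beta and T cell) and 0.0413 (smooth muscle and metalloproteinases). None held: adjusted p = 0.216 with an estimated correlation for the red blood cell and Paneth lists, 0.3302 for the adipocyte list and 0.570 to 0.757 for the others, while fry called the red blood cell and Paneth lists (0.0257). The other 16 lists had adjusted p between 0.0870 and 0.763. All PBS mice shared 1 sample prefix that no other mouse carried, so control kind and prefix cannot be told apart here. They were also 12 weeks old, as was 1 of the 8 IgG mice, and no age term was fitted.

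The calls of the red blood cell, both interferon, adipocyte, Paneth, B cell, dendritic and WNT lists stayed without each of the 12 libraries. The absorptive, cytotoxic, MHC class II and T cell calls ended without the 2 libraries of doubtful sex (0.423, 0.174, 0.504 and 0.647), and the smooth muscle list then turned (0.00455). Without the sex covariate the T cell and smooth muscle calls ended (0.0859 and 0.207). The goblet call ended without APP control 2 (0.489), the cytotoxic call without APP control 2 or 3 (0.0556 and 0.0667), the MHC class II call without APP control 3 (0.0707) and the mast cell call without AP control 2 or APP control 1 (0.0512 and 0.0534). The TGF-beta call ended without AP control 2 or 6 or APP control 6 (0.143, 0.0735 and 0.0503). The metalloproteinase call ended without AP control 2, 3 or 6 or APP control 2 or 6 (0.143, 0.0537, 0.276, 0.0556 and 0.297), the smooth muscle call without AP control 1, 3, 5 or 6 or APP control 1, 3 or 6 (0.0619 to 0.607), and the T cell call without AP control 4 or 5 or any APP control other than 6 (0.0603 to 0.344).

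The mean log2 CPM of the interferon-gamma response genes lay between 3.87 and 5.84 in 5 tumours (AP control 1 and 6, APP control 2 and 3 and APP treated 2) and between 6.88 and 8.15 in the other 14. The gap between them was 1.05, and the next largest gaps, both within the 5, were 0.93 and 0.78. In the 5 tumours the cytotoxic lymphocyte score was −0.23 or less, and in the 14 it was 0.58 or more. Whether these are separate clusters was not tested, and the relation was measured within the 14 alone, each score centred on its group. There Pearson's r was 0.835 (95% bootstrap interval 0.508 to 0.950, permutation p = 0.00026, adjusted p = 0.0013 over 5 relations) and Spearman's rho 0.798 (permutation p = 0.00102), two-sided. These permutations moved the centred scores freely between groups. They ignore the degrees of freedom spent on the group means, so these p-values are likely too small. Without the 2 tumours farthest from the median of the interferon score r was 0.722. Each sample prefix holds at most 4 of the 14 tumours, too few for its own value. With scores centred on the prefix instead, a test added after the first values were seen, r was 0.813 (permutation within prefixes p = 0.00678) and rho 0.789 (p = 0.00580), and 0.871 (p = 0.00514) and 0.789 (p = 0.0214) on group and prefix together (adjusted p = 0.00678 for both r). Without the 2 farthest tumours these r were 0.705 and 0.774. The p-values on group and prefix together have the same limit.

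**Figure D4:**
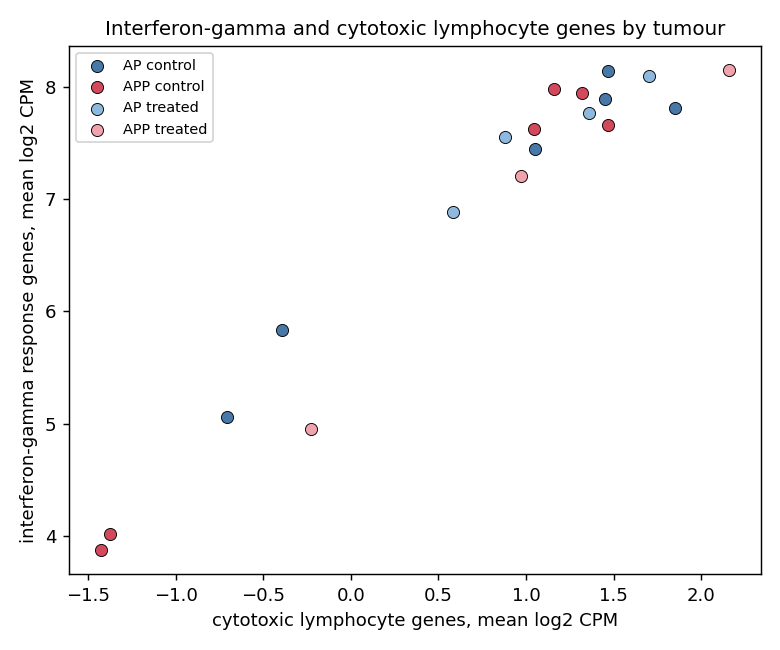
Mean log2 CPM of the interferon-gamma response genes (vertical axis) against that of the cytotoxic lymphocyte genes (horizontal axis) in each of the 19 tumours, coloured by genotype and treatment. The 5 tumours at 5.84 or below on the vertical axis lie apart from the other 14, which lie at 6.88 or above.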

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

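The tests for Sox17, Nefl and Nefm, Ifi202b, Sccpdh and Gstp-ps, the sources of Prox1 transcript, the share of epithelium and the cytotoxic lymphocytes were chosen after the results were seen, as were the 2 libraries of doubtful sex, which were singled out from the data, and the rise from 20 to 30 splits in 4 comparisons. In 180 groups of values, 14 held a library far from the others, where chance gives 9.

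For the first pattern weighed, the genes called between APP and AP control tumours, chance is argued against but not excluded. The real split called 86 genes and gave the most of 100 splits (1 as large, the real one), with 15 as the highest other. That is the smallest share that 100 splits can give. Alleles carried with the engineered locus would put called genes near Prox1, but 3 of 85 lay within 20 Mb of it, 3.53% (95% interval 0.734 to 9.97), against 1.25% of the genes tested (one-sided Fisher p = 0.0902), too few for alleles near Prox1 to account for most calls. Alleles farther away or on other chromosomes lie outside this test. So does 1 call without a position, which had the same values as Gstp-ps (log2 fold change −6.01 for each) and may be Gstp-ps counted again. For those 3, Gstp-ps (1.90 Mb from Prox1), Sccpdh (10.4 Mb) and Ifi202b (16.1 Mb), a linked allele and an effect of the deletion cannot be told apart, and Ifi202b did not follow the genotype in every tumour (1 count in APP control 5 and APP treated 4, 124 to 1390 in the other 7 APP tumours). Without the 2 libraries of doubtful sex the median called gene kept 99.0% of its log2 fold change, though fewer libraries left 26 calls. These genes were called in a fit that held both libraries, and only 1 library left each group, so this share could hardly fall far. It therefore does not settle whether the sex labels matter, and no fit set sex from the Y-linked genes. More blood endothelial cells or enteric neurons would move their other genes too, but these had medians of 0.26 (SD 0.33) against 4.06 for Sox17 and −0.15 (SD 0.83) against 3.74 for Nefl.

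The second pattern is the Prox1 transcript in APP tumours, which kept 74.8% of the AP control mean. Lymphatic endothelial cells are argued against as its source, since their 7 genes summed to at most 30.04% of Prox1 in any of the 9 APP libraries (Ccl21a 9.97, Pdpn 7.88 and Flt4 5.30 CPM). Enteroendocrine genes summed to between 15.6% and 179% of Prox1 (Sct 101, Pyy 10.2 and Chgb 7.49 CPM), so cells of that kind that kept the gene stay open. Sct, with an SD of 100 CPM over these libraries, made up most of the mean sum, and every other gene of the list averaged 10.2 CPM or less. Transcript of a recombined gene and tumour cells that kept the gene cannot be told apart either, because gene counts hold no exon.

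For the third pattern, the spread of interferon-gamma response genes between tumours, library depth is argued against: thinning every library to the smallest total lowered the SD of 1.43 by 0.25%. A lower share of epithelium would raise the other cell types alike, and among the 14 tumours the lowest of 4 correlations was 0.351 (permutation p = 0.216), which leaves it open, although without the 2 farthest tumours smooth muscle went from 0.354 to −0.0956 and endothelial genes from 0.351 to 0.171. More cytotoxic lymphocytes may contribute, with a correlation of 0.835 in these tumours, as a hypothesis found and tested on the same data. The correlations for epithelium and for lymphocytes leave out the 5 low tumours, so they do not show what sets those apart. Control kind ranked these genes lower in PBS tumours (26 of 26 members, adjusted p = 9.18e-08, lost at adjusted p = 0.570 with an estimated correlation), but of the 5 low tumours AP control 1 and 6 were IgG and APP treated 2 was treated, while the PBS tumours AP control 2 and 3 stood at 7.89 and 7.44. All 5 low tumours held Y-linked genes at the male level (113 to 169 CPM), including APP control 3, which is labelled female. Other tumours at that level stood among the 14, as did every tumour at the female level. Sex and age stay open and untested.

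For the other counts, the real split for genotype under treatment called the most genes (1 of 35 splits, real 11, highest other 2). That is the smallest share that 35 splits can give, so chance is argued against but not excluded. There 847 genes had an unadjusted p under 0.05 where 880 are due by chance, and 5 of the 7 fits without 1 treated library called 0. For the other 4 comparisons the real count was 0, so each of the 30 splits called at least as many (30 of 30) by construction and the splits say nothing about chance: the highest other count was 2 for treatment in AP, 5 for treatment in APP, 0 for the difference of the treatment effect and 1 for PBS against IgG. By edgeR these counts of 0 had 340, 291, 256 and 1832 genes at an unadjusted p under 0.05, and DESeq2 called 4, 5, 1 and 180 and limma-voom 0, 0, 0 and 1.

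Single libraries lay far from their group on the log2 CPM scale. AP control 6 was lowest for Mmp14 (7.26, next 8.05) and metalloproteinases (3.71, next 4.83), and highest for epithelial genes (9.65, next 9.06), absorptive genes (7.97, next 4.97) and the share of the 10 most abundant genes (10.8%, next 6.40%). APP control 5 was lowest for Ifi202b (−3.16, next 3.38), Duox1 (0.081, next 1.53) and tuft cell genes (0.43, next 0.98). APP control 6 was lowest for WNT target and stem cell genes (5.95, next 6.53) and blood endothelial genes (3.34, next 3.96). Highest were AP treated 4 for Ifi202b (−3.35, the other 3 at 0 counts), AP treated 2 for S100g (5.12, next 3.20) and AP treated 3 for Khdc1a (1.86, next −0.18). AP control 3 had the lowest total of its group, 21.2 M counts against 27.96 M in the next.

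A difference of the treatment effect between genotypes appeared in 7 lists by the preset correlation: proliferation (0.000263), T cell (0.00577), red blood cell (0.00654), hypoxia (0.0109), blood endothelial (0.0109), neutrophil (0.0170) and cytotoxic lymphocyte genes (0.0172), each with adjusted p = 0.960 with an estimated correlation. Y-linked genes, which the comparisons do not use, summed to 107 CPM in AP control 3 and 113 CPM in APP control 3, both labelled female, so the labels of sex or the libraries are in doubt there.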

How the results depend on the processing

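The robust dispersions, the fits without both libraries of doubtful sex and the averaged contrasts were chosen after the data were seen. Over named genes and lists, 3416 values kept their direction and side of the threshold, 275 lost their call, 2 gained one (Sox17 for genotype under treatment without the sex covariate, 4.72, and Cdh5 for genotype in controls without AP control 5, 1.51) and 103 changed sign, and of the counts 239 stayed within 1.5 times and 67 moved. Counts of genes for treatment in AP, treatment in APP and their difference were 0 by edgeR in every setting that kept edgeR other than the groups of the comparison alone in AP (1), with 340, 291 and 256 genes at an unadjusted p under 0.05, and limma-voom called 0. With the list without Sox17, also chosen after the data were seen, blood endothelial genes in APP control versus AP control kept an adjusted p of 0.000478 and blood endothelial genes in APP treated versus AP treated one of 3.26e-10. These fits used the preset correlation, and with Sox17 in the list both calls were lost, at adjusted p = 0.904 and adjusted p = 0.806 with an estimated correlation. Prox1 in APP against AP controls lay between −0.52 and −0.36 over the alternatives. Depth limits the genes near the floor, such as Ifi202b, Ctla4 and Cd40lg. The cause was not tested for the changes below. Settings with fewer libraries lower the power of the test by construction, but some of them raised the counts, up to 97 genes and 12 lists for genotype in controls.

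With an estimated correlation 0 lists were called in each of the 6 comparisons by camera, and with fry 0 lists in each other than PBS against IgG, which had 2. The replicate block with sex called 71 genes for genotype under treatment and 503 for the averaged genotype, and it could not be fitted for PBS against IgG. No label says that equal replicate numbers pair samples. Between AP and APP control, however, 5 of 6 same-numbered pairs shared a sample prefix. In 4 of the 6 the same-numbered tumour was the closest match by deviation from the group mean.

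With DESeq2, 270 genes were called for genotype in controls, 4 genes were called for treatment in AP, and 5 genes were called for treatment in APP. In the same setting, 1 gene was called for the treatment difference, 116 genes were called for genotype under treatment, and 632 genes were called for the averaged genotype. In the same setting, 4 genes were called for the averaged treatment, and 180 genes were called for PBS against IgG. With limma-voom, 53 genes were called for genotype in controls, and 1 gene was called for PBS against IgG. For genes of at least 5 CPM on average, 25 genes were called for genotype in controls, 0 genes were called for genotype under treatment, and 172 genes were called for the averaged genotype. Without the sex covariate, 137 genes were called and Vegfa turned to −0.12 for genotype in controls, Vegfa turned to −0.066 and Cd40lg turned to 0.30 for treatment in AP, and Kdr turned to −0.0131 and Flt1 turned to 0.0104 for treatment in APP. In the same setting, Cd40lg turned to −0.0405 for the treatment difference, and 36 genes were called for genotype under treatment. With sex and the sample prefix, Vegfa turned to −0.0468 for genotype in controls, Mmp14 turned to 0.0465 and Angpt2 turned to 0.0747 for treatment in AP, and 15 lists were called for the treatment difference. In the same setting, 0 genes were called, 14 lists were called and Cd40lg turned to 0.24 for genotype under treatment. With IgG controls alone, 13 genes were called, 10 lists were called, interferon-gamma response genes turned (adjusted p = 0.00642), Mmp14 turned to 0.12, Vegfa turned to −0.28, Angpt2 turned to −0.061, Kdr turned to −0.37 and Irf1 turned to 0.13 for genotype in controls, Mmp14 turned to 0.17 and Vegfa turned to −0.0743 for treatment in AP, and interferon-gamma response genes turned (adjusted p = 0.00449), type I interferon response genes turned (adjusted p = 0.0252), MHC class II genes turned (adjusted p = 0.824), Flt1 turned to 0.12, Cd40 turned to −0.12 and Stat1 turned to −0.00738 for treatment in APP. In the same setting, neutrophil genes turned (adjusted p = 0.174), cytotoxic lymphocyte genes turned (adjusted p = 0.672), Mmp14 turned to −0.14, Angpt2 turned to 0.18, Cd40 turned to −0.0355 and Il1b turned to −0.61 for the treatment difference, 2 genes were called, Mmp14 turned to −0.0235 and Cd40lg turned to 0.16 for genotype under treatment, and 173 genes were called for the averaged genotype. Without both libraries of doubtful sex, 26 genes were called, Vegfa turned to −0.079 and Kdr turned to −0.0784 for genotype in controls, Mmp14 turned to 0.0414 for treatment in AP, and 0 genes were called and Cd40lg turned to 0.41 for genotype under treatment. In the same setting, smooth muscle genes turned (adjusted p = 0.00455), Vegfa turned to −0.33 and Flt1 turned to −0.21 for PBS against IgG. With the groups of the comparison alone, 32 genes were called for genotype in controls, 1 gene was called for treatment in AP, and 0 genes were called for genotype under treatment. With robust dispersions, 7 genes were called for genotype under treatment.

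Leaving out 1 library at a time gave these ranges of log2 fold changes, adjusted p of lists, and counts. For genotype in controls the range was genes called from 20 to 97, lists called from 2 to 12, Vegfa −0.11 to 0.0825, Kdr −0.0871 to 0.36, Cd40 −0.57 to 0.36. For treatment in AP the range was Mmp14 −0.29 to 0.037, Vegfa −0.10 to 0.12, Angpt2 −0.36 to 0.0636, Cd40lg −0.61 to 0.48, Ms4a1 −0.0318 to 2.64, Bank1 −0.29 to 2.11. For treatment in APP the range was lists called from 7 to 16, interferon-gamma response genes 2.17e-09 to 0.961, type I interferon response genes 3.18e-07 to 0.883, macrophage genes 0.000912 to 0.961, Prox1 −0.0703 to 0.14, Vegfa −0.63 to 0.0938, Kdr −0.0016 to 0.29, Flt1 −0.21 to 0.13, Tek −0.28 to 0.00773, Cd40 −0.00725 to 1.16, Cd22 −0.20 to 1.77, Klrb1c −0.43 to 1.70, Cxcl11 −0.69 to 1.53, Irgm1 −0.32 to 1.43, Stat1 −0.26 to 0.95. For the treatment difference the range was lists called from 4 to 16, Vegfa −0.64 to 0.0735, Angpt2 −0.43 to 0.0586, Cd40lg −0.0457 to 2.01, Gzmb −0.16 to 1.88. For genotype under treatment the range was genes called from 0 to 5, lists called from 5 to 17, Mmp14 −0.00514 to 0.31, Vegfa −0.64 to 0.0776, Angpt2 −0.15 to 0.27, Cd40lg −0.27 to 0.20. For PBS against IgG the range was genes called from 0 to 1, Prox1 −0.00945 to 0.18, Vegfa −0.12 to 0.37.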

Other observations

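The contrasts averaged over the other factor, and the genes named here, were chosen after the results were seen. Averaged over control and treated tumours, 230 genes were higher and 90 lower in APP than in AP. Wnt11, which encodes a secreted WNT ligand, had a log2 fold change of 1.85 ± 0.23 (SE, adjusted p = 0.000288), Sox17 4.22 ± 0.52 (adjusted p = 0.000288), Cpxm2 2.93 ± 0.29 and Matn4 2.47 ± 0.25 (both 5.91e-05). Nefm had 3.91 ± 0.42 (9.08e-05), Dpp6, a potassium channel partner, 3.47 ± 0.36, Hist1h2bc −1.48 ± 0.14 (both 5.91e-05) and Gpr182 −1.73 ± 0.21 (0.000233). Blood endothelial genes were positive in 18 of 19 (median 0.55), with 3 members higher over all genes and 7 adjusted over the list alone (list adjusted p = 2.20e-12, but adjusted p = 0.857 with an estimated correlation). The 320 calls became 632 with DESeq2, 172 for genes of at least 5 CPM and 173 with IgG controls alone.

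Kit, a receptor tyrosine kinase of mast cells and interstitial cells, and its ligand gene Kitl both rose in APP control tumours: Kit from 15.9 ± 1.62 to 30.3 ± 10.1 CPM (1.09 ± 0.17, adjusted p = 0.00394) and Kitl from 96.5 ± 20.7 to 196 ± 51.8 CPM (1.03 ± 0.22, adjusted p = 0.0432; SD, n = 6 each). In APP against AP treated tumours the log2 fold changes were 0.52 and 0.61, and neither gene was called. The mean score of the mast cell list was 2.10 in AP and 1.95 in APP control tumours. Averaged over genotype, the treatment called 0 genes by edgeR, with 443 at an unadjusted p under 0.05, and DESeq2 called 4 (Gcg, Pla2g2d, Igkv8-18 and Gm10241) and limma-voom 0.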
